A study of Homo sapiens with 2 samples.

How the data were processed

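CUT&Tag was performed on H1299 cells, a human lung carcinoma cell line, with an antibody to hnRNP K and with control IgG. In CUT&Tag an antibody directs the transposase Tn5 to chromatin, and the tagged DNA is sequenced. Each antibody had 1 library, so nothing could be compared with a spread between replicates. The deposited tables hold peaks of the hnRNP K library with their nearest genes and functional terms. Signal of the IgG library was not analysed here. The genome build hg38 and the peak caller MACS2 are named, without version or role, in the submitters' processing notes. The aligner, the caller's settings and the number of reads per library are not given in the sources used here.

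The measurement columns of the deposited peak table did not hold what their headers say, and they were read by their values. The column headed fold enrichment held −log10 of a p-value, with a smallest value of 2.00 among the deposited peaks. The column headed P value held 10 to the power of minus the summit pileup, which was a whole number (within 1e-06) for every peak above the limit of number precision. The column headed FDR held 10 to the power of minus the fold over local background. The column headed pileup held the summit position, which lay inside the peak in 100% of rows. With this reading, the Poisson upper tail of the pileup over the local background equalled the deposited −log10 p within a relative tolerance of 0.001 for 100% of 74540 peaks. For the other 48 peaks the pileup was beyond the limit of number precision and was left out. The table therefore gave a p-value, a pileup and a fold for each peak but no q-value. These per-peak values are the authors' and were used only to describe, rank and filter peaks within this list. The local background of each peak was computed as (pileup + 1)/fold − 1.

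Genomic classes were taken from the deposited annotation, whose promoter class reaches 2 kb from a transcription start site (TSS), per the values of its distance column. A random placement on the genome sequence and a search for C-rich motifs at summits had been planned and were not run, since no genome sequence was used here. In place of random placement, an added measure shifted all summits of a chromosome by a common random distance of at least 1 Mb, 200 times. It compared the number of summits within 1 kb of the 5′ end of a protein-coding gene with the mean over the shifts. Strand was needed for this, and an alternative used either end of all protein-coding genes.

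Gene positions, types and current symbols came from the RefSeq gene table of GRCh38.p14, the same build as hg38. That table has no strand, so strand was taken from the deposited annotation: 15379 of its 17754 gene names were matched by symbol or unique synonym on the same chromosome. A gene was counted as occupied when a peak overlapped the 1 kb either side of its 5′ end. Any annotated TSS of a gene had been planned. The RefSeq table gives a single start and end per gene, so a peak at a TSS further inside the gene was not counted. A gene of unknown strand was counted as unoccupied when neither end had a peak and was left out when either end had one, which removed 1361 of 19974 protein-coding genes. Genes with a strand are those to which the authors assigned a peak, so the share in the background depends on this rule. An alternative counted the removed genes as occupied.

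A total of 29 gene lists was fixed before the data were examined, from general knowledge. They hold 945 matched genes, 18 of them in more than 1 list, and 2 symbols were not matched. A list's share of occupied genes was set against 10000 random lists with the same number of genes of each gene type. A share above the 97.5th percentile is called high and a share below the 2.5th is called low. Chance alone would put about 1.45 of 29 lists outside that band. These percentiles describe 1 library and are not tests of replicated samples. Random lists and the intervals below treat genes as independent. Neighbouring genes of a list, such as HOX genes, were not handled as a group, so both can be too narrow. Shares carry 95% exact (Clopper-Pearson) binomial intervals, which cover counting error only. Median differences carry 95% intervals from 1000 bootstrap draws over peaks. Biological process terms of 20 to 500 genes came from the deposited functional annotation. For each term, genes with a promoter-class peak were counted among all genes in the table and compared with 10000 random gene sets.

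Genes named in the text followed a rule fixed before the data were examined. It took the 15 genes with the highest fold at a promoter peak, whose summit had to lie within 1 kb of the TSS. It also took the 10 highest folds over 10 kb from an annotated TSS and the 5 genes with most summits between their bounds. For each list it took the 2 members with the strongest promoter peak and the first 2 in alphabetical order without one. HNRNPK, MYC, SRC and EIF4E were named whatever their values. Of the genes this rule takes, a few are not reported here. Gene functions are given as background. Peaks outside chromosomes 1 to 22 and X entered only the size of the peak set and the closing section.

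Alternatives planned beforehand were the strongest 25% of peaks by fold, peaks merged when under 1 kb apart, a 3 kb promoter window, overlap of 50% of the peak, summits instead of overlaps, the genes the authors assigned to promoter peaks, pileup instead of fold, and protein-coding genes only. Peaks with p of 1e-05 or less, a 1 kb promoter class, counting of genes of unknown strand, either end of all protein-coding genes and random lists matched on chromosome were added after seeing the data. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.

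The calculations were tested on simulated data. All of 5000 simulated peaks, built with the formulas that the decoding inverts, were decoded. For the lists, occupancy was itself simulated, independently for each gene. Of 200 random lists of genes drawn from the 19974 protein-coding genes, 5.0% were called high or low, and 90.0% of 20 lists enriched in occupied genes were called high. These checks cover the calculation and not the strand rule or the dependence of neighbouring genes. Summits placed uniformly gave a promoter fold over shifts of 1.01 for 73968 peaks.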

Results

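CUT&Tag was used to map where hnRNP K, an RNA- and DNA-binding protein with affinity for C-rich sequence, lies on the chromatin of H1299 lung carcinoma cells. The series comprised 2 libraries, 1 made with an antibody to hnRNP K and 1 with IgG. With 1 library per antibody there were no replicates, and no difference below has a replicate check. The peak list of the hnRNP K library is the measurement described, and the IgG signal was not analysed here. Fold values are the authors' fold of each summit over its local background.

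The list held 74588 peaks that covered 45.6 Mb, of which 73968 lay on chromosomes 1 to 22 and X. Most peaks were low. The median summit rested on 6 fragments, and 50.1% of summits on 6 fragments or fewer. The median width was 485 bp (interquartile range 385 to 670 bp) and the median fold over local background was 2.92 (2.64 to 3.40). The highest fold was 25.2. A p of 1e-05 or less was reached by 13628 peaks, or 18.3%. The local background had a floor of 1.06 fragments, at which 25.6% of the peaks with a readable pileup lay, and its median was 1.35. Single weak peaks therefore carry little weight, and the comparisons below are of classes and gene groups.

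The series addressed the genomic distribution of hnRNP K. By the authors' annotation, 47.5% of the 73968 peaks were intergenic (95% interval 47.1% to 47.9%) and 39.5% lay in introns (39.1% to 39.8%). Promoters held 7449 peaks, a share of 10.1% (9.85% to 10.3%). Exons held 2.45% and transcript ends 0.491%. The promoter share depended on peak strength. It was 2.97% in the tenth of peaks with the weakest p and 32.9% in the tenth with the strongest, while the intron share went from 45.1% to 19.8%. Among the 13373 peaks with p of 1e-05 or less, 27.3% were at promoters (26.5% to 28.0%) and 46.0% remained intergenic. Within 1 kb of the 5′ ends of protein-coding genes with a known strand lay 5712 summits, against a mean of 752 (SD 32.0 over 200 shifts) when the summits were shifted along each chromosome. This was a 7.60-fold excess, and none of the shifts gave more than 821. Genes with a known strand are those to which the authors assigned a peak, which raises this value. At either end of all protein-coding genes, without that selection, the excess was 3.65-fold (7303 summits against a mean of 2002). At 5′ ends of known strand it was 21.1-fold for peaks with p of 1e-05 or less and 15.4-fold for the strongest 25% by fold.

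**Figure D1:**
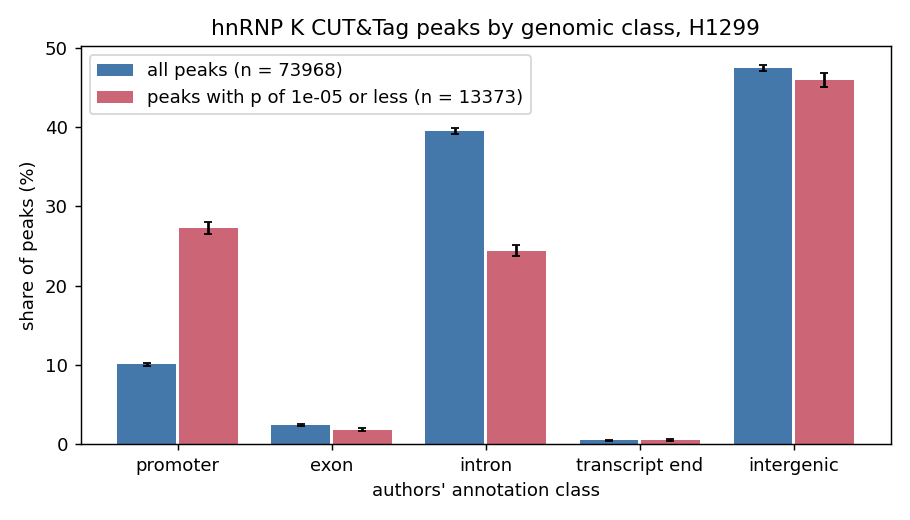
Share of peaks (%) in each class of the authors' annotation for all 73968 peaks on chromosomes 1 to 22 and X (blue) and for the 13373 peaks with p of 1e-05 or less (red), with 95% exact binomial intervals. The promoter share is 10.1% for all peaks and 27.3% for the stronger ones, and the intron share is 39.5% and 24.4%.

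Promoter peaks were also taller. Their median fold was 3.40 and that of the 66519 other peaks 2.92, a difference of 0.486 (95% bootstrap interval 0.457 to 0.486). These medians are the folds of summits of 6 and 5 fragments at the background floor. Many folds are tied at such values, which is why the upper limit equals the estimate. The median summit held 11 fragments at promoters and 6 elsewhere. Among peaks with p of 1e-05 or less the difference in median fold was only 0.0519 (0.00118 to 0.101), with medians of 4.28 and 4.23.

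At promoters, summits were most frequent at the start of transcription and lay more often downstream of it than upstream. Of the 7434 summits within 2 kb of an annotated TSS, 60.7% lay within 500 bp and 36.0% lay upstream. The fullest 50 bp interval began at the TSS and ran to 50 bp downstream, with 367 summits, against a mean of 31.9 in the 10 outermost intervals. Over all peaks, the median distance to the annotated TSS was 54.6 kb (bootstrap interval 53674 to 55428 bp). It was 31872 bp for peaks with p of 1e-05 or less and 62813 bp for the strongest 25% by fold, so the direction depended on the measure of strength.

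**Figure D2:**
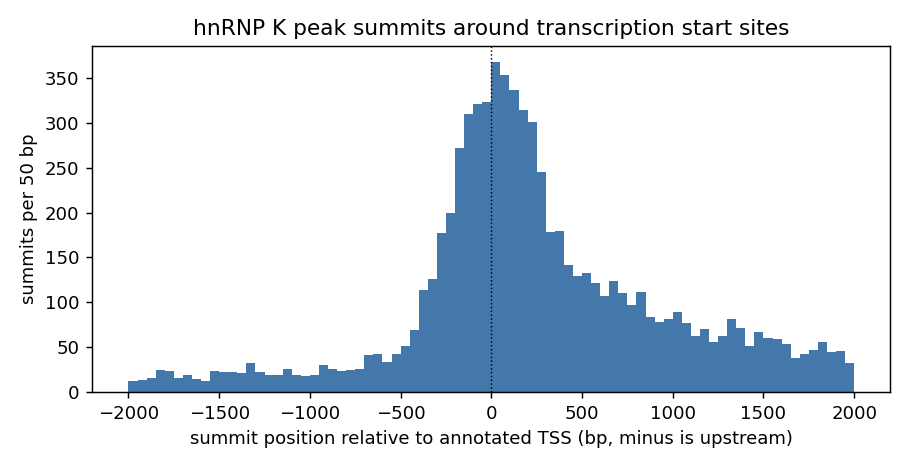
Number of peak summits per 50 bp (vertical axis) by position relative to the annotated transcription start site in bp, minus being upstream (horizontal axis). The highest bar, 367 summits, covers the 50 bp just downstream of the start, and 36.0% of the 7434 summits lie upstream.

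The 15 genes with the highest promoter folds had values of 7.94 to 13.5. The peak of FARP2, an activator of small GTPases, had a fold of 11.4 and 244 fragments at its summit, which lay at −502 bp from the TSS (hg38 chromosome 2, 241355438 to 241356138). ENSA, an inhibitor of a protein phosphatase, had a fold of 10.4 (chromosome 1, 150629195 to 150629954). The transcription factor gene ATF7 had 8.79, RIOK1, a kinase of ribosome assembly, 8.71, and SPOP, a substrate adaptor of a ubiquitin ligase, 8.46. RRM2B, a subunit of ribonucleotide reductase, had a fold of 8.39 with 72 fragments (chromosome 8, 102238819 to 102239726). FBXO27, GANC, VMAC and PRMT2 had folds of 8.13, 8.06, 7.94 and 7.94. On chromosome X, the peak of the deacetylase gene HDAC6 had a fold of 7.99. The remaining 4 of these 15 peaks lay at genes with near-identical copies, among which reads are hard to place. MTRNR2L8, which resembles mitochondrial ribosomal RNA, had the highest fold at 13.5 (chromosome 11, 10509348 to 10509950). EEF2KMT and FAM86B2, members of 1 gene family, had 9.03 and 8.16. A peak on chromosome 1 (228557860 to 228558330), with a fold of 8.48, is assigned by the authors' annotation to RNA5SP162, a ribosomal RNA pseudogene. RefSeq places the gene of that symbol on chromosome 4.

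The gene for hnRNP K itself carried a peak. It spanned the TSS of HNRNPK (chromosome 9, 83979598 to 83981070), with a fold of 5.92 and 17 fragments at a summit 208 bp downstream. MYC, a proto-oncogene whose transcription has been linked to hnRNP K, had a promoter peak with a fold of 3.67 and 19 fragments, its summit 825 bp downstream of the TSS (chromosome 8, 127735198 to 127736804). EIF4E, the cap-binding translation factor, had a peak with a fold of 3.52 and 11 fragments (chromosome 4, 98928261 to 98929982). SRC, a tyrosine kinase gene, had no peak within 1 kb of its 5′ end. Its intronic peaks lay 12285 and 40118 bp downstream of the TSS, with folds of 2.96 and 2.67.

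Genes with a promoter peak were compared by group. Without IgG signal, binding of hnRNP K and open chromatin cannot be told apart at these promoters. Of 18613 protein-coding genes, 6555 had a peak within 1 kb of the 5′ end, a share of 35.2%. This share was 39.6% when genes of unknown strand with a peak at either end were counted. It depended on which peaks were kept. The share was 19.6% with p of 1e-05 or less and 19.9% with the strongest 25% of peaks by fold. A 3 kb window gave 44.4%. In the main count, 14 of 29 lists were high, 5 were low and 10 lay between. A peak was counted for each gene whose window it met, whichever gene the authors assigned it to. A gene given below without a peak lacked one within 1 kb of the 5′ end of its RefSeq bounds. Start sites further inside such a gene were not searched and may have a peak. The peaks given below for SNRPA, CDC45, GPI, XPC, HOXC4 and LPCAT3 were assigned to C19orf54, UFD1L, AC010504.2, LSM3, RP11-834C11.12 and C1S, in that order.

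With all peaks, splicing factor, hnRNP family and translation initiation genes had the highest shares. Promoter peaks were found at 31 of 35 splicing factor genes (88.6%, 95% interval 73.3% to 96.8%), 23 of 26 hnRNP family genes (88.5%, 69.8% to 97.6%) and 26 of 31 translation initiation factor genes (83.9%, 66.3% to 94.5%). All 10000 random lists lay below each of these counts. The ranking moved in some alternatives. Splicing factor genes had 20 of 36 (55.6%) with p of 1e-05 or less and with the strongest 25% by fold. In both, the list of genes linked to hnRNP K had 7 of 12 (58.3%). With the authors' promoter genes, that list (66.7%) lay above splicing (65.9%) and translation initiation (65.7%). The strongest peaks were at SF1 and SNRPA among splicing factors, with folds of 7.44 and 7.0, and at RALY and HNRNPD in the hnRNP family, with 7.75 and 7.34. EIF3J and EIF5A led the initiation factors with 6.66 and 5.97. PRPF19, PRPF3, HNRNPH1, HNRNPL, EIF3C and EIF3F had none. Cytosolic ribosomal protein genes had a peak in 44 of 68 (64.7%, 52.2% to 75.9%), with folds of 7.23 at RPS19 and 5.54 at RPL39 and no peak at RPL10A or RPL11. With p of 1e-05 or less, 28 of 73 (38.4%) had a peak, and with the strongest 25% by fold 27 of 73 (37.0%) had a peak. Genes that host small nucleolar RNAs had one in 8 of 14 (57.1%, 28.9% to 82.3%), against 16% for genes of the same types. The list was high in all 8 alternatives, but its share ran from 4 of 19 (21.1% against 7.80%, strongest 25% by fold) to 16 of 22 (72.7% against 27.0%, genes of unknown strand counted). It was 5 of 19 with p of 1e-05 or less and 6 of 22 (27.3% against 10.5%) with the authors' promoter genes. The chaperone gene HSPA8 and ZFAS1 had folds of 5.48 and 5.17, while EEF2 and EPB41L4A-AS1 had no peak. All random lists lay below the main counts of 44 and 8 too.

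Other groups used by most dividing cells were also high. Cell cycle genes had a promoter peak in 26 of 41 (63.4%, percentile 99.99), among them CDC45 and E2F3 with folds of 6.11 and 5.69, but not BUB1 or CCNA2. Proteasome genes had one in 17 of 29 (58.6%, percentile 99.4), led by PSMD1 and PSMA5 with 5.36 and 5.12, and not at PSMA1 or PSMA3. Nuclear-encoded respiratory chain genes had one in 28 of 48 (58.3%, percentile 99.9), led by NDUFA6 and ATP5F1B with 6.78 and 6.03, and not at ATP5F1D or COX4I1. Glycolysis genes had one in 14 of 22 (63.6%, percentile 99.6), led by the glucose transporter gene SLC2A1 with 6.74 and GPI with 5.09, and not at ALDOC or HK2. The respiratory chain list was no longer high with p of 1e-05 or less or with the authors' promoter genes, nor glycolysis with the strongest 25% of peaks.

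Several regulated groups were high as well. KRAB zinc finger genes, which encode repressors, had a promoter peak in 27 of 38 (71.1%, percentile 99.995), with folds of 6.13 at ZNF140 and 5.56 at ZNF41 and none at ZNF114 or ZNF133. Immediate early genes of the growth response had one in 18 of 26 (69.2%, percentile 99.98), with 4.73 at EGR1 and 4.61 at KLF10 and none at ATF3 or EGR2. Targets of p53, a factor that H1299 cells lack, had one in 16 of 26 (61.5%, percentile 99.6). RRM2B and XPC led this list with folds of 8.39 and 6.78, and AEN and BAX had no peak. The list of genes whose transcription has been linked to hnRNP K had one in 8 of 12 (66.7%, 34.9% to 90.1%, percentile 98.4), led by HNRNPK and TK1, the latter with 4.83, and not at BCL2 or CDKN1A. This call ended with a 3 kb window and when genes of unknown strand were counted. Immediate early genes were no longer high in the strongest 25% of peaks. Mesenchymal genes had a peak in 15 of 28 (53.6%, percentile 97.8), with 4.43 at ACTA2 and 4.38 at TWIST1 and none at COL1A2 or COL3A1, and stayed high in 3 of 8 alternatives.

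The 5 low lists were fibroblast and endothelial markers, olfactory receptors, liver and pancreas genes, epithelial genes and HOX genes. None of the 22 fibroblast and endothelial markers, among them CDH5 and CLDN5, had one (interval 0% to 15.4%). Olfactory receptor genes had 1 in 37, at OR1A2 with a fold of 2.92, and OR10A2 and OR10G2 had none. Liver and pancreas genes had 2 in 28, at SST and CPA1 with folds of 2.92 and 2.78, and none at AFP or ALB. Epithelial genes had 2 in 27 (7.41%, 0.910% to 24.3%), with 3.86 at CLDN1 and 2.04 at CLDN4 and none at the cadherin gene CDH1 or at CLDN3. HOX genes had 3 in 33, with 4.10 at HOXC4 and none at HOXA10 or HOXA11. Counting genes of unknown strand gave 9 of 39 HOX genes (23.1%), 4 of 29 epithelial genes (13.8%) and 4 of 30 liver and pancreas genes (13.3%). A 3 kb window gave 7 of 28, 9 of 26 and 3 of 24 in the same order. The percentiles of these 5 lists were 0.09 or lower. The epithelial call was the only one that any alternative ended. It lay between the limits with a 3 kb window and with the authors' promoter genes.

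**Figure D3:**
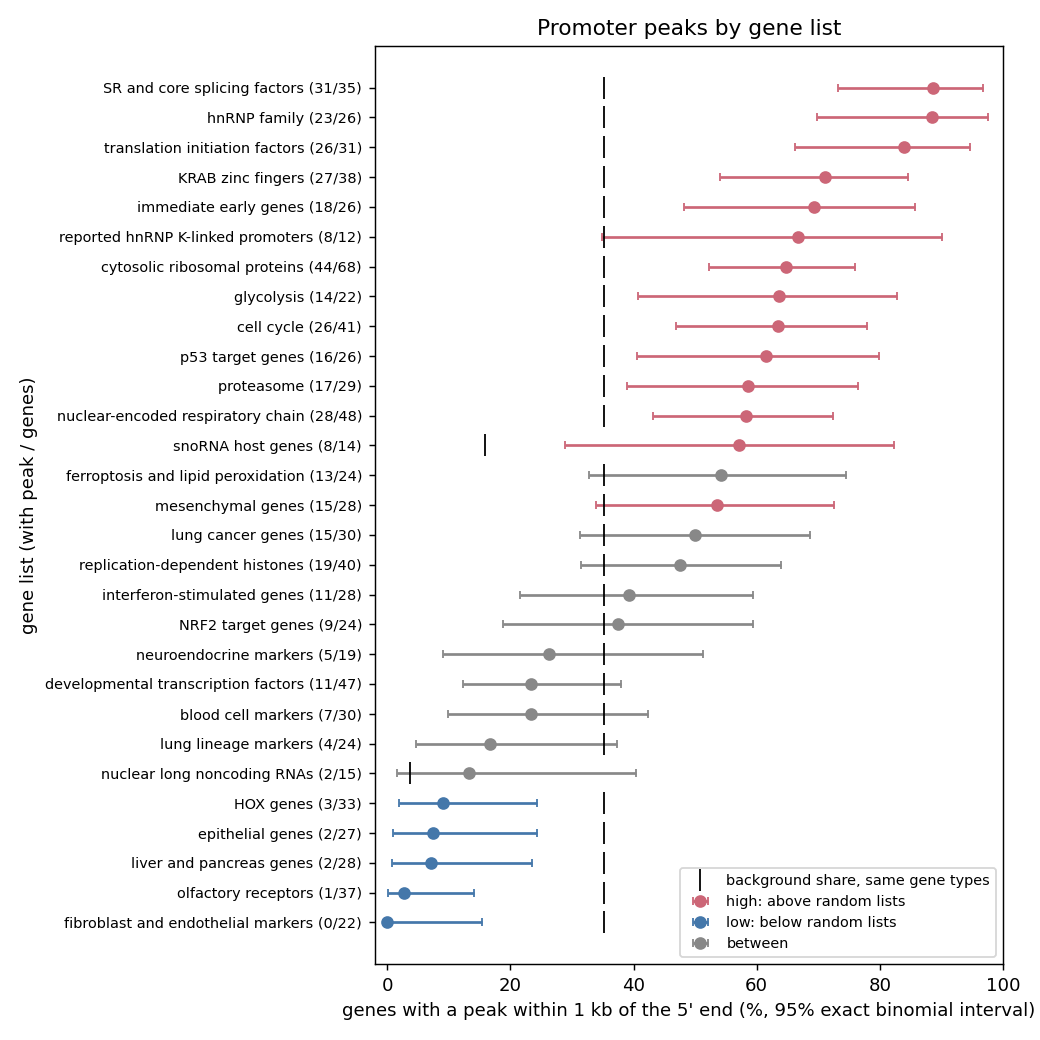
Share of each list's genes with a peak within 1 kb of the 5′ end (%, points) with 95% exact binomial intervals, and the background share of genes of the same types (black ticks). Points are red for high lists, blue for low lists and grey for lists between, judged against 10000 random lists. Splicing, hnRNP and translation initiation genes lie above 80% and the 5 low lists below 10%.

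The other 10 lists lay within the range of random lists. They included lung lineage markers with 4 of 24 (16.7%, percentile 2.57), where ETV5 and CAV1 had folds of 4.83 and 3.78 and AGER and AQP5 had no peak. Neuroendocrine markers had 5 of 19 (SYT1 3.62 and POU3F2 3.29, none at CALCA) and blood cell markers 7 of 30 (SPI1 3.18 and CD68 3.16, none at CD163). Developmental transcription factor genes had 11 of 47 (23.4%, percentile 4.38), with 4.26 at DLX1 and none at EN1 or EN2. This list was low in 5 of 8 alternatives. Replication-dependent histone genes had 19 of 40 (47.5%), led by H4C12 and H4C11 with 7.69 and 5.08 and without H1-1 and H1-3. This list was high when genes of unknown strand were counted (32 of 53, 60.4%, percentile 99.93) and when the summit had to lie in the window (percentile 97.53). Targets of NRF2, the antioxidant regulator, had 9 of 24, with 7.38 at NQO1 and 6.45 at UGDH and none at ABCC2 or ABCC3. Ferroptosis genes had 13 of 24 (54.2%, percentile 96.9), with 5.65 at LPCAT3 and 4.26 at VDAC2 and none at AIFM2 or ALOX15. Lung cancer genes had 15 of 30, with 4.75 at RBM10 and 4.68 at MDM2 and none at ALK or ARID1A. Interferon-stimulated genes had 11 of 28 (PSMB9 4.76 and STAT2 4.39, none at BST2 or HLA-B), and nuclear long noncoding RNAs 2 of 15 (13.3%, against 3.78% for genes of the same types, percentile 95.3; TUG1 3.43 and HOTTIP 3.03, none at CASC15 or CCAT1). Of the 8 alternatives, lung cancer genes were high in 2, ferroptosis genes and nuclear long noncoding RNAs each in 1, while blood cell markers were low in 2 and neuroendocrine markers in 1.

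The functional terms of the authors' annotation gave a comparison beside the fixed lists. Of 9747 genes with a biological process term, 4207 had a promoter-class peak (43.2%). Only genes to which the authors assigned a peak are in this background. A gene without a promoter-class peak enters it through a peak elsewhere. Low shares may therefore partly reflect which genes have such peaks. Among 378 terms, 29 were high and 60 were low, where chance would give 9.45 on each side. Ranked by the distance from the mean of the random sets in their SDs, which favours large terms, translation came first among high terms, with 90 of 145 genes (62.1%). It was followed by splicing through the spliceosome (34 of 49), nucleosome assembly (30 of 42), vesicle-mediated transport (65 of 108), translational initiation (32 of 47) and ribosomal RNA processing (24 of 33). DNA repair had 63 of 108 and protein folding 41 of 64. Lowest on the same scale were G-protein coupled receptor signalling, with 96 of 402 genes (23.9%), and ion transport, with 68 of 281 (24.2%). Sensory perception of smell had 26 of 120, neuropeptide signalling 2 of 34 and potassium ion transport 19 of 81. Many terms share genes, so these counts are not independent. The number of high terms was 14 with p of 1e-05 or less and 18 with the strongest 25% of peaks.

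Away from promoters, the 10 highest folds lay at the ends of chromosomes or in intergenic sequence 503416 bp or more from an annotated TSS. No repeat annotation was used, so whether the latter peaks lie in repeats was not tested. The 10 strongest peaks over 10 kb from a TSS had folds of 19.4 to 25.2. The highest was on chromosome 17 (25918702 to 25921905), at −1373857 bp from the TSS of its nearest gene WSB1, and 2 more lay in the same interval with folds of 22.6 and 21.6. The first peak of chromosome 3 (9998 to 10856, nearest gene CHL1-AS2) had a fold of 23.9. The last peaks of chromosomes 22, X, 18 and 12, nearest to RABL2B, WASIR1, AC139100.3 and a Y RNA gene, had folds of 22.4, 20.6, 20.1 and 20.1. The remaining peaks lay on chromosome 10 (40555438 to 40557985, nearest gene IGKV1OR10-1, fold 19.6) and on chromosome 3 (93470358 to 93470813, nearest gene PROS1, fold 19.4).

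The 5 genes with most summits within their bounds were long by those RefSeq bounds. Summits were counted between the bounds even where other genes lie inside them. NRXN3, a synaptic adhesion gene, held 53 summits over 1698 kb and DLGAP1, a synaptic scaffold gene, 51 over 959 kb. RANBP2, GPHN and the immunoglobulin heavy chain locus IGH held 46, 44 and 41, over 1123, 1227 and 1293 kb. These were 31.2, 53.2, 41.0, 35.9 and 31.7 summits per Mb in the order named. All peaks on their chromosomes came to 26.9 per Mb on chromosome 14 (NRXN3, GPHN and IGH), 25.4 on chromosome 18 (DLGAP1) and 21.1 on chromosome 2 (RANBP2). The genes were picked for their many summits, which tilts this comparison towards higher values for them.

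Peak density differed between chromosomes. It was highest on chromosome 19, with 56.7 peaks per Mb, followed by chromosomes 17 (37.9), 12 (37.6), 22 (36.8) and 8 (35.2). It was lowest on chromosomes X (7.97), 13 (9.07) and 4 (12). Chromosome 19 also had the highest density of protein-coding genes, 24.8 per Mb. Per protein-coding gene, the order differed, with 7.54 peaks on chromosome 18 and 7.14 on chromosome 8 against 2.28 on chromosome 19 and 1.47 on X. H1299 is aneuploid, so these densities are not levels of binding.

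**Figure D4:**
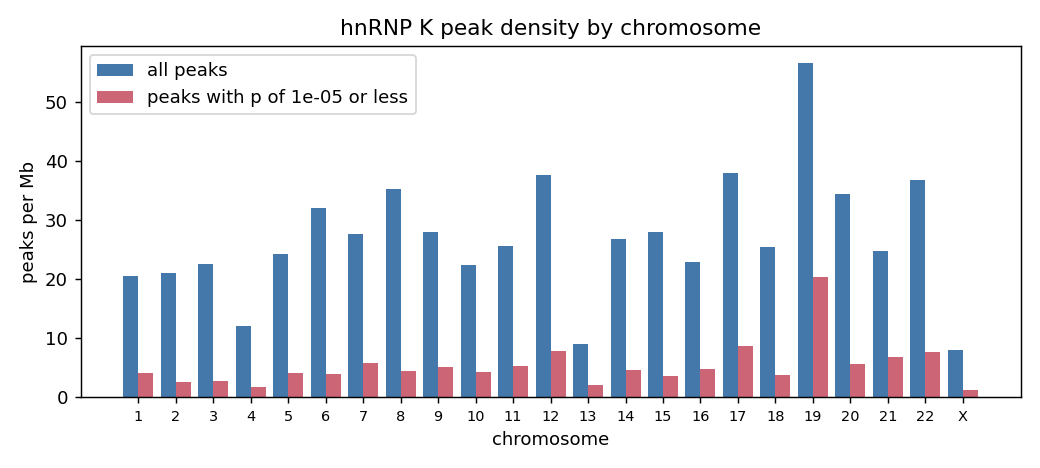
Peaks per Mb of the span between the first and last peak of each chromosome, for all peaks (blue) and for peaks with p of 1e-05 or less (red). Chromosome 19 has 56.7 and 20.4 per Mb, and chromosome X has 7.97 and 1.33.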

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

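The test of repeats below was chosen after the result was seen. Peaks on unplaced sequence, meaning all sequence outside chromosomes 1 to 22, X and Y, entered the report only in the size of the peak set. Of 574 such peaks, 40.4% had p of 1e-05 or less, against 18.1% on chromosomes 1 to 22 and X.

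Of the 46 peaks that were the first or the last of their chromosome, 14 had p of 1e-20 or less (30.4%, interval 17.7% to 45.8%), against 1.11% of 73922 other peaks, and 10 of the 20 smallest p-values belonged to them. A candidate explanation is that reads of a repeat pile up on its few copies in the assembly, and it needs other repeat-rich sequence to be high as well. On unplaced sequence, 69 of 574 peaks had p of 1e-20 or less, 10.7 times the share on chromosomes 1 to 22 and X. That this sequence is rich in repeats was assumed and not checked. A biological alternative is that hnRNP K lies on the C-rich strand of telomeres, to which some of the 14 end peaks could belong; without IgG values the explanations cannot be told apart.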

How the results depend on the processing

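Alternatives using p of 1e-05 or less, the 1 kb promoter class, counting of genes of unknown strand, chromosome-matched lists, either end of all genes and the promoter fold over shifts were chosen after seeing the data. With p of 1e-05 or less, 13628 peaks remained; on chromosomes 1 to 22 and X these were 13373, 27.3% at promoters, with a promoter fold of 21.1, a median TSS distance of 31872 bp, 8 low lists in place of 5 and 14 high terms in place of 29. Fewer peaks enter by construction, and the cause of the other changes was not tested. With the strongest 25% by fold, 21476 peaks remained (ties included). Their lower limit was a fold of 3.40, which a summit of 6 fragments has at the background floor of 1.06. This set therefore includes low peaks. Of the 21201 on chromosomes 1 to 22 and X, 17.6% were at promoters, with a promoter fold of 15.4. Their median TSS distance was 62813 bp, against 54560 bp for all peaks, and there were 18 high terms. A 3 kb window gave a promoter share of 11.4% and a fold of 3.49, and a 1 kb class gave 7.99%, as the window's size sets. Either end of all protein-coding genes gave a fold of 3.65; it removes the selection of genes by peaks and adds 3′ ends. The difference in median fold between promoter and other peaks stayed above 0 in all 5 alternatives, from 0.0519 with p of 1e-05 or less to 0.486 after merging, and 5 fragments by pileup. The number of high lists was 12 to 15. Of 14 high lists, 9 were high in all 8 alternatives, and of 5 low lists 4 were low in all 8. Over lists and alternatives, 205 calls were the same, 13 were lost and 14 were gained, none changing direction. Of 71 named promoter peaks, 10 were absent with p of 1e-05 or less and 9 from the strongest 25%. The planned −log10 q threshold, the matching on promoter CpG and GC and the C-rich motif search were not run, for want of a q-value and of sequence. For the gene lists, any annotated TSS was planned and a single 5′ end per gene was used. No paired analysis was possible because each antibody had 1 library. Low pileups limit what single peaks show.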

Other observations

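All tests in this part except that of 1 kb windows were chosen after the result was seen. Distal peaks, over 10 kb from a TSS, differed in density between stretches of the same chromosome, which were picked after their values were seen. On chromosome 8, the 5 intervals of 5 Mb from 5 to 30 Mb held 65 to 102 distal peaks each (mean 81.4), and the 8 intervals from 40 to 80 Mb held 191 to 292 (mean 235). On chromosome 3, intervals from 60 to 80 Mb held 3 to 10 (mean 6.75) and those from 125 to 145 Mb held 134 to 169 (mean 150.0). As for whole chromosomes, these densities are not levels of binding, since H1299 is aneuploid.

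The local background of the peaks had a regular form. Above its floor it moved in steps of 0.0159 fragments (100% of 44261 values within 0.05 steps), which equals a fragment of 318.7 bp counted at both ends over 10 kb, and the narrowest peak was 318 bp wide. Background taken from the IgG library would, with the caller's usual windows of 1 kb, put many values on multiples of 10 steps, but 10.8% lay there where 10% would by chance. Background taken from the hnRNP K library itself would never fall below what a peak's own fragments add to a 10 kb window, and 0 of 1496 peaks tall enough to show it fell below. The values are thus consistent with peaks called without IgG as control, as a hypothesis, since the caller's settings are not given in the sources used here.

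The 6 lists of widely used genes named here had high shares of promoter peaks. Over all genes, not per list, chance hits of many weak peaks fall short of the overall share of genes with a peak, since peaks shifted along their chromosome met either end of 12.9% of all protein-coding genes, 29.5% of the observed share of 43.7%. Another candidate explanation is that Tn5 enters open promoters whatever the antibody. The list linked to hnRNP K, at 66.7%, lay inside the range of 58.3% to 88.6% of the 6 lists (ribosome, splicing, translation initiation, proteasome, respiratory chain and cell cycle). With the authors' promoter genes, the linked list was again at 66.7% and lay just above the range of the 6 lists, 42.4% to 65.9%. With 12 genes its interval spans the first range, so this comparison cannot decide. Without IgG signal, binding of hnRNP K and open chromatin cannot be told apart for these lists.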
